A study of Mus musculus with 8 samples.

How the data were processed

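Gene expression was measured by RNA sequencing of 8 libraries, 1 per group: heart and soleus of wild type mice and of mdx mice given vehicle, cardiosphere-derived cells (CDC) or exosomes (EXO), all aged 11 to 12 months. Per the labels' protocols, RNA was extracted from tissue with a column kit and libraries were made with a stranded messenger RNA kit. Per the submitters' processing notes, Bowtie, RSEM and edgeR were used with genome build mm10, without roles, order or versions. How many animals went into a library, the time of collection, the dose and the route of delivery are not given in the sources used here.

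The deposited table holds 1 expression signal per gene and library, per the labels TMM-normalized CPM, that is, read counts divided by library sizes that the authors had adjusted with the trimmed mean of M-values. It has 24054 genes, of which 5157 are at 0 in all 8 libraries, and 27 symbols that a spreadsheet had turned into dates. The columns sum to between 866157 and 1431310, as TMM-scaled values need not share a total. Every value was a whole multiple of the smallest value of its column (100.0% within 0.02 reads), so the reads behind each value were recovered by division: 9477281 in heart wild type, 12648142 in heart vehicle, 11023691 in heart CDC, 11478782 in heart EXO, 14284441 in soleus wild type, 14300201 in soleus vehicle, 13037657 in soleus CDC and 12845215 in soleus EXO. In these libraries 1 read was worth 0.0717 to 0.100 CPM.

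The values were used as deposited. Differences between libraries are log2 ratios of CPM + 1 within a tissue, for genes with a mean of at least 1 CPM over its 4 libraries. Genes with a ratio of at least 2-fold (1 on the log2 scale) were counted in each direction. No test across conditions was made, because each group has 1 library, and heart and soleus were not used as replicates of each other. Fold changes of single genes carry 95% exact conditional (Clopper-Pearson) intervals from the recovered reads of the libraries compared. They cover counting error only, not the variation between animals, and a comparison of reads between libraries compares those libraries, not the conditions. Where a library had 0 reads, the fold is given as the lower limit of this interval. Shares of genes carry Wilson intervals.

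The lists of genes, 44 with 914 genes of which 894 were in the table, covered muscle disease, fibre type, metabolism, stress, immunity, growth, cell types and checks of the labels. They were fixed before the data were examined, and 42 of them were meant to be ranked. The median log2 difference of a list was ranked among 10000 random lists of the same size matched on mean expression in 20 bins, and a list with at least 5 measured genes was called apart below percentile 2.5 or above 97.5. This describes the libraries and is no test of a condition. In each tissue 39 lists could be ranked. None of the mitochondrially encoded genes has a row in the table, fewer than 5 lymphocyte genes were measured in either tissue, and the keratinocyte list could be ranked only in soleus and the list of neighbouring tissues only in heart.

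The genes named in the text were chosen by a rule written before the data were examined: symbols other than Gm or LOC with digits, those ending in Rik and -ps pseudogenes, with a mean of at least 5 CPM in the tissue, and the 10 largest differences in each direction for each comparison with wild type or vehicle, the 6 largest for CDC against EXO, the 8 largest shared by both treatments, the 8 largest with wild type or vehicle apart from the other libraries, up to 4 members of each list with the largest difference, and Dmd, Utrn, Nnt and the sex-linked genes. Rn45s, Pf4, Itgb3, F5, Egr1, Cyr61 and the clock genes of the figure were chosen after their values were seen. Positions and sequences come from GRCm38/mm10 with GENCODE vM21. A gene was called uncertain when at least 50% of its transcript positions lie in 50-base stretches found in another annotated gene, and 95.1% of the genes tested in heart and 95.2% in soleus could be checked for this.

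The differences of CDC and of EXO from vehicle share the vehicle library. The correlation, covariance, overlap and share of genes toward wild type with no effect at all were therefore simulated 20 times from the mean of the 4 libraries, with counting error alone and with an assumed biological coefficient of variation of 0.2, and independent overlaps were computed from the counts in each direction. The counting step was tested on simulated data before use. Of 50 genes planted at each fold for CDC against vehicle, 0 were called at 1.5-fold in either tissue, 98.0% in heart (13257 genes) and 100.0% in soleus (13404 genes) at 3-fold, and 100.0% at 4-fold and 8-fold. The planted genes had a mean of at least 5 CPM and counting error alone, so variation between animals was not covered. Of 100 random lists of 20 genes, 5 were called without a shift and 81 with a shift of 0.3.

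Alternatives chosen before the data were examined were a pseudocount of 0.5 or 5 CPM, no filter on low values, a mean of at least 5 CPM, libraries rescaled to the same total, median-of-ratios scaling within a tissue, and random lists matched in 5 bins. After seeing the data, counts without genes that share at least 50% of their sequence and counts that also pass a test on counting error were added. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.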

Results

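Messenger RNA was sequenced from heart and from soleus, a slow postural muscle of the hindlimb, of C57BL/6 mice aged 11 to 12 months. The mdx mouse carries a nonsense mutation in Dmd, the gene of dystrophin, and is the standard mouse model of Duchenne muscular dystrophy. Each tissue had 4 libraries, from wild type mice, mdx mice given vehicle, mdx mice given cardiosphere-derived cells (CDC) and mdx mice given exosomes, the small vesicles secreted by such cells (EXO). The series asks how the cells and their vesicles change gene expression in dystrophic heart and skeletal muscle. There was 1 library per group and therefore no replicate, so every value below describes a library, and no difference carries a test across animals.

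The libraries held 9477281 (heart wild type) to 14300201 (soleus vehicle) recovered reads on annotated genes, and a value of 5 CPM stood for 49.9 to 69.7 reads. Titin (Ttn), the giant spring protein of the sarcomere, took 9.45% to 10.5% of the reads in the heart libraries and 23.1% to 29.1% in the soleus libraries. Differences are given as log2 ratios of CPM + 1 or as folds of CPM, and the intervals are 95% intervals of counting error only. After removal of genes with a mean under 1 CPM in the tissue, 13262 genes remained in heart and 13387 in soleus. Between simulated unchanged libraries 0.85 genes in heart and 0.95 in soleus were at least 2-fold apart with counting error alone, and 189 and 195 with an assumed biological coefficient of variation of 0.2.

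Dystrophin transcript was lower in all 6 mdx libraries than in wild type of the same tissue. Dmd (chromosome X, 82948870 to 85206141, GRCm38/mm10 with GENCODE vM21) stood at 769 CPM in wild type heart and at 330.1 in vehicle, 302 in CDC and 293 in EXO heart. In soleus it stood at 1659.7 CPM in wild type and at 488 in vehicle, 519 in CDC and 563 in EXO. Wild type over vehicle was 2.33-fold in heart (2.25 to 2.42) and 3.4-fold in soleus (3.3 to 3.5). Utrn, which encodes the dystrophin relative utrophin, was 1.12-fold lower in vehicle than in wild type heart and 1.23-fold higher in vehicle than in wild type soleus. The dystrophin complex list, with Dmd and Utrn among its members, had medians of -0.02 in heart and -0.01 in soleus for vehicle against wild type. Xist lay between 372 and 584 CPM in the 8 libraries, and Ddx3y, Eif2s3y, Kdm5d and Uty had 0 reads in each, so the libraries did not differ in the sex these genes show. Nnt, deleted in part in one C57BL/6 substrain, lay between 1091 and 1185 CPM in heart and was 1.78-fold lower in vehicle than in wild type soleus, but shares 96.3% of its sequence with another annotated gene and is uncertain.

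**Figure D1:**
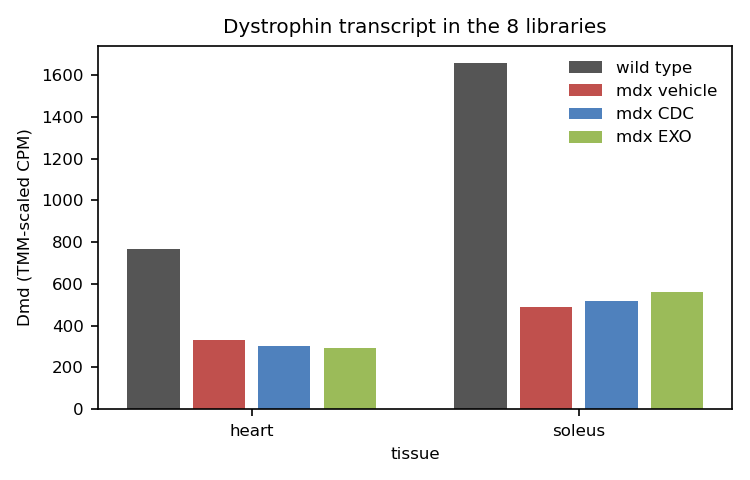
Dystrophin transcript (Dmd, TMM-scaled CPM) in each of the 8 libraries, 1 bar per library, grouped by tissue. The 6 mdx bars lie between 293 and 563 CPM, below the wild type bars of 769 CPM in heart and 1659.7 CPM in soleus.

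Connective tissue, immune and blood lists had the largest medians in the soleus of mdx mice given vehicle against wild type soleus, all higher. Collagen I genes were more than 6-fold higher, macrophage, interferon, antigen presentation and complement genes were higher nearly throughout, and regeneration genes were mostly higher. Genes of slow fibres and of fatty acid use were lower. In total 1104 genes were at least 2-fold higher in vehicle than in wild type soleus and 182 at least 2-fold lower.

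All 42 measured genes of the extracellular matrix and fibrosis list were higher in vehicle soleus, 33 of them at least 2-fold, with a median difference of 1.62. Col1a1 was 7.51-fold higher (7.16 to 7.89) and Col1a2 6.53-fold, the chains of collagen I. Comp and Fmod, matrix proteins that organise collagen fibrils, were 7.0-fold and 6.53-fold higher. The tendon and cartilage list shares members with this group and had a median of 2.09 with 13 of 13 genes higher, among them Kera at 18.1-fold. Without the genes that also sit on the tendon or fibroblast lists, the matrix median was 1.60, with 36 of 36 genes higher. This takes out listed genes only, so it cannot tell whether tendon tissue contributed to the rest. The fibroblast list had a median of 0.61, with 16 of 16 genes higher.

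Immune genes stood higher in vehicle soleus as well. Macrophage and monocyte genes had a median of 1.36, with 25 of 29 higher and 19 at least 2-fold higher. Emr1, the macrophage marker F4/80, went from 3.01 CPM in wild type to 29 in vehicle (9.66-fold), and Lgals3, a lectin of activated macrophages, was 7.62-fold higher. The interferon response list had 29 of 29 genes higher and a median of 1.34, with the antiviral genes Oasl2 at 11.2-fold, Mx1 at 9.39-fold and Irf7 at 8.09-fold. Antigen presentation had 15 of 15 genes higher and a median of 1.20, including the class II genes H2-Eb1 (6.05-fold) and Cd74 (4.87-fold). Complement and coagulation had a median of 1.21 with 15 of 18 higher, and C3, the central complement protein, was 6.30-fold higher. Cytokines and NF-kB targets (median 0.72), immediate early genes (0.76), glucocorticoid targets (0.71), adipocyte genes (0.43), smooth muscle and pericyte genes (0.34), growth factors and receptors (0.31), endothelial genes (0.28) and clock genes (0.23) also lay above matched random lists. Neutrophil and mast cell genes, at a median of 0.22 over 5 genes, did not stand apart.

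Regeneration genes had a median of 0.51 with 19 of 23 higher. Myh8, the perinatal myosin heavy chain that regenerating fibres express, went from 15.2 to 136 CPM (8.96-fold, 7.59 to 10.6), and Myl4, an embryonic light chain, was 6.99-fold higher. Slow fibre genes had a median of -0.82 with 14 of 15 lower, including Myl3 (2.09-fold lower) and Myl2 (1.97-fold lower), the slow light chains. Fast fibre genes split around a median of 0.30: Myh4, the IIB myosin, was 6.26-fold higher and Myh1, the IIX myosin, 3.42-fold lower, from 6014 to 1758 CPM. Fatty acid use had a median of -0.45 with 27 of 30 lower, among them Lpl, which releases fatty acids from lipoproteins (2.21-fold lower), and Acadm, a beta-oxidation enzyme (2.02-fold lower). Glycolysis lay slightly higher (0.06). The erythroid and blood list had 9 of 9 genes higher and a median of 1.35, with Hba-a1 at 3.33-fold, although the haemoglobin genes share sequence and their split is uncertain. Nuclear oxidative phosphorylation genes (median -0.22, 41 of 44 lower), ribosomal protein genes (-0.22) and heat shock genes (-0.36, 12 of 12 lower) were lower but not apart, since random lists of like abundance were lower too. Calcium handling (-0.28), cardiac stress genes (-0.27), keratinocyte and skin (-0.16), muscle atrophy and proteolysis (-0.09), cardiac ion channels (-0.07), oxidative stress (-0.06), unfolded protein response (0.03), ventricular genes (0.05), p53 targets (0.09), Schwann cell and nerve (0.13), hypoxia targets (0.19), atrial genes (0.21) and cell cycle (0.33) were not apart either.

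Among single genes, the largest differences upward in vehicle soleus included Hp, the acute-phase protein haptoglobin (1.5 to 24.7 CPM, 16.4-fold), Slfn4, a gene of activated myeloid cells (16.1-fold), Serpinb1a, an inhibitor of neutrophil proteases (11.3-fold), and Dclk1, a microtubule-associated kinase (8.37-fold). Emb, Pik3ap1 and Chil1 had 4 to 5 reads in wild type, and their folds of 33.8 (13 to 125), 27.7 (11.6 to 86.2) and 23.9 (10.03 to 74.7) are correspondingly wide. Downward, Rp1 was 34.7-fold lower, Dach2, a transcription factor tied to muscle innervation, 14.2-fold, Lrtm1 12.2-fold, Efcab6 12.0-fold, Ces5a 10.7-fold, Ano3 10.1-fold, Tecrl 7.52-fold, and Lars2, the mitochondrial leucyl-tRNA synthetase, 9.89-fold. Amd1 had no reads in vehicle soleus, which makes it at least 199-fold lower, and BC002163 was 42.8-fold lower, but 87.6% and 72.6% of their sequence is shared with other genes. Wild type soleus stood apart from all 3 mdx soleus libraries by at least 2-fold at 406 genes, 86 with wild type highest and 320 with wild type lowest, against 47 for vehicle, 195 for CDC and 58 for EXO. Lrtm1, Dach2, Rp1, Polq, Cyp26b1, which breaks down retinoic acid, and Lgi1 were among those highest in wild type, and Serpina3n, Timp1, Lgals3, Fbln7 and Oasl2 among those lowest. With every library rescaled to the same total, the median of all genes in this comparison moved from -0.0025 to 0.32 and the split became 1750 higher and 74 lower, so the lower medians above hold relative to that shift.

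The heart of mdx mice given vehicle differed from wild type heart by much less. Matrix, fibroblast, complement and glucocorticoid-responsive genes were modestly higher in the vehicle heart, and atrial muscle genes, immediate early genes and the myosin Myh7 were lower. The vehicle heart had 144 genes at least 2-fold higher and 127 at least 2-fold lower than wild type heart. Wild type heart stood apart from all 3 mdx hearts at 36 genes, against 34 for vehicle, 30 for CDC and 27 for EXO.

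The matrix list in heart had 35 of 41 genes higher and a median of 0.28, with Tnc, a matrix protein of injured tissue, 5.05-fold higher and Timp1, an inhibitor of matrix proteases, 3.47-fold higher. Glucocorticoid targets had a median of 0.60 with 7 genes at least 2-fold higher. Fkbp5, a sensitive glucocorticoid target, went from 14.7 to 70.9 CPM (4.84-fold, 4.07 to 5.78), and Zbtb16 was 2.36-fold higher. Fibroblast genes (0.34), the unfolded protein response (0.33), complement and coagulation (0.31), hypoxia targets (0.28), cell cycle (0.24), macrophage and monocyte genes (0.22), ribosomal proteins (0.21), fast fibre genes (0.17), glycolysis (0.08, 16 of 24 higher), erythroid and blood (0.66) and the list of lung and thymus neighbours of the heart (0.64, 5 genes) lay above matched random lists. The cell cycle median was 0.0039 with a mean of at least 5 CPM and that of the neighbours 0 with no filter on low values, both without a call. Immediate early genes had a median of -0.53 with 18 of 24 lower, including Jun (2.62-fold lower), while Socs3, a feedback inhibitor of cytokine signalling on the same list, was 7.32-fold higher. The atrial list had 10 of 12 genes lower and a median of -0.39: Myl7, the atrial light chain, went from 37.3 to 7.60 CPM (4.90-fold lower), Sln was 4.54-fold lower and Myl4 3.92-fold lower. Interferon response (-0.24), clock genes (-0.18), cardiac ion channels (-0.17) and fatty acid use (-0.10) were also lower.

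Lists without a call in heart included cardiac stress genes (-0.10) and slow fibre genes (-0.06), although Myh7, the slow myosin that stressed rodent hearts re-express, was 2.21-fold lower in vehicle (2776 to 1255 CPM) and Acta1, skeletal actin, 2.58-fold lower. Muscle regeneration (-0.01), calcium handling (-0.06), muscle atrophy (-0.01), nuclear oxidative phosphorylation (0.03), oxidative stress (0.09), heat shock (0.03), p53 targets (0.16), neutrophil and mast cell (-0.17), cytokines (-0.16), antigen presentation (-0.12), growth factors (-0.04), endothelial (-0.0013), smooth muscle (-0.06), adipocyte (-0.05), Schwann cell (0.06), tendon (0.23) and ventricular genes (-0.06) were likewise not apart. Single genes with the largest differences upward were Akr1b3, aldose reductase (7.76 to 107 CPM, 13.8-fold, 11.0 to 17.6), the platelet genes Tubb1 (14.9-fold), Itga2b (13.8-fold) and Ppbp (12.1-fold), the water channel Aqp4 (7.60-fold) and Arrdc2 (5.23-fold). Xkrx (10.8-fold), Cyp26b1 (10.02-fold), Edn3, an endothelin (8.69-fold), and Cxcl1, a neutrophil chemokine (7.26-fold), were lower. Akr1b3, Acta2 (smooth muscle actin, 2.45-fold), Aqp4 and Cenpf, a mitotic protein (3.62-fold), were higher in vehicle and at least 2-fold above wild type in all 3 mdx hearts.

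The CDC soleus library combined higher immediate early, glucocorticoid-responsive and macrophage genes with mostly lower regeneration genes and lower collagen I genes than vehicle soleus. Rrad, Socs3, Mt1 and Mt2 were more than 10-fold higher. Dbp, Per3, Myh8 and Col1a1 were at least 3-fold lower. There were 337 genes at least 2-fold higher and 253 at least 2-fold lower than in vehicle.

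Immediate early genes had 23 of 24 higher and a median of 1.10, with Atf3, a stress-induced transcription factor, at 8.43-fold and Myc at 8.39-fold. Cytokines and NF-kB targets had a median of 1.11 with 17 of 20 higher, among them Il4ra (5.50-fold), the interleukin-4 receptor, and Ccl2 (7.33-fold), a monocyte chemokine. Glucocorticoid targets had 15 of 16 higher and a median of 0.83, with Fkbp5 at 3.75-fold, the metallothioneins Mt1 (28.5 to 311 CPM, 10.9-fold, 9.81 to 12.2) and Mt2 (10.9-fold), and Pdk4, which holds back glucose oxidation, at 4.42-fold. Macrophage and monocyte genes had 27 of 29 higher and a median of 0.72, including Cd68 (2.86-fold) and Gpnmb (2.71-fold), while interferon response (0.11) and antigen presentation (0.12) were not apart. Complement and coagulation (0.55), adipocyte genes (0.40), heat shock (0.35, several members uncertain through shared sequence), oxidative stress (0.28), the unfolded protein response (0.27), ribosomal proteins (0.17) and muscle atrophy and proteolysis (0.17) were higher. Ppargc1a, the coactivator of mitochondrial biogenesis, was 4.81-fold higher, although fatty acid use (0.08) as a list was not apart.

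Muscle regeneration was lower in CDC than in vehicle soleus (median -0.43, 16 of 23 lower). Its median against wild type, however, was 0.53 in CDC and 0.51 in vehicle soleus. Myh8 went from 136 CPM in vehicle to 44.7 in CDC (3.06-fold lower). Chrng, the fetal acetylcholine receptor subunit, was 4.13-fold lower than in vehicle, and the stretch-responsive Ankrd1 3.27-fold higher. The matrix list was split: its median was -0.16 with 27 of 42 lower, Col1a1 was 3.11-fold lower (3.01 to 3.21), and Thbs1, an injury-responsive gene, was 2.85-fold higher. Tendon and cartilage (-0.71), erythroid and blood (-1.59), clock genes (-0.36), atrial genes (-0.30), growth factors (-0.13), fast fibre genes (-0.12) and calcium handling (-0.07) were lower. Other large differences upward were Rrad, a small GTPase that damps calcium channels (33.2 to 592 CPM, 17.8-fold, 16.2 to 19.7), Socs3 (13.2-fold), Sphk1 (14.5-fold), Ptx3 (13.9-fold), Sox9 (12.5-fold), Rpl30 (11.8-fold) and Zfp697 (8.17-fold). Downward they included Dbp, a clock output factor (124 to 14.6 CPM, 8.55-fold), Per3 (4.69-fold), Hlf (5.10-fold), Bcl6b (4.65-fold) and Ky, a muscle gene whose loss causes kyphoscoliosis (4.31-fold).

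The CDC heart library had lower matrix, fibroblast and glucocorticoid-responsive genes than the vehicle heart. Fkbp5, Socs3 and Tnc were more than 3-fold lower. The platelet genes Ppbp, Tubb1 and Itga2b were also lower, while Pf4, another platelet gene, differed less (14.1 to 9.49 CPM). At the 2-fold level 90 genes were higher and 183 lower.

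Glucocorticoid targets had 14 of 16 genes lower and a median of -0.82. Fkbp5 went from 70.9 to 13.7 CPM (5.16-fold lower, 4.38 to 6.13) and Fam107a was 5.70-fold lower. The matrix list had 34 of 41 genes lower and a median of -0.33, with Tnc 3.13-fold and Thbs1 2.03-fold lower. Fibroblast genes had 14 of 17 lower and a median of -0.38, including the proteoglycan Dcn (1.45-fold lower). Tendon and cartilage (-0.94, 7 genes), lung and thymus neighbours (-0.62, 5 genes), complement and coagulation (-0.33), clock genes (-0.28), muscle regeneration (-0.21), macrophage genes (-0.18), ribosomal proteins (-0.16, 34 of 34 lower), antigen presentation (-0.16) and growth factors (-0.15) were lower too. With no filter on low values the tendon median was -0.078 and the medians of the neighbours and of muscle regeneration 0, all without a call. Higher were immediate early genes (0.33), with Fos at 2.43-fold, interferon response (0.27), heat shock (0.26), smooth muscle and pericyte (0.16), endothelial genes (0.13), with the VEGF receptor Kdr at 2.41-fold (160 to 386 CPM), and erythroid and blood (0.65). Cardiac stress genes (0.09) were not apart, yet the natriuretic peptide genes Nppa (2.07-fold) and Nppb (1.92-fold) were higher.

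Largest upward in the CDC heart among genes with unshared sequence were Cxcl1 (9.38-fold), Xkrx (26.5 to 133 CPM, 5.03-fold), Hlx (4.24-fold), Hey1, a Notch target (3.35-fold), St8sia4 (3.33-fold), Kctd12b (3.28-fold) and Aplnr, the apelin receptor (2.92-fold). Largest downward were Ppbp (15.05-fold), Tubb1 (13.9-fold), Itga2b (9.05-fold), Map3k6 (6.36-fold) and Arrdc2 (6.24-fold). Ccl21a (32.8-fold), BC002163 (12.2-fold) and Hbb-bs (11.7-fold) were higher but share sequence with other genes, and Etohi1 (18.6-fold lower), Erdr1 (45.9-fold lower, 15.4 to 225) and OTTMUSG00000016609 (at least 39.7-fold lower) could not be checked for shared sequence.

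In the EXO soleus library, macrophage, antigen presentation, interferon, complement, matrix and endothelial genes were lower than in vehicle, and nuclear oxidative phosphorylation and fast fibre genes were higher. Macrophage genes and antigen presentation genes lay about a log2 unit lower. Socs3 and Serpina3n were higher, as in the CDC soleus. There were 111 genes at least 2-fold higher and 419 at least 2-fold lower than in vehicle.

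Macrophage and monocyte genes had 26 of 29 lower, 15 at least 2-fold, and a median of -1.03, including Trem2 (4.70-fold lower), Mpeg1 (3.35-fold) and Ctss, a lysosomal protease (61.1 to 18.6 CPM, 3.29-fold). Antigen presentation had 15 of 15 lower and a median of -1.04, with H2-Aa 3.30-fold lower. The matrix list had 40 of 42 lower, 14 at least 2-fold, and a median of -0.85. Fmod went from 319 to 44.5 CPM (7.17-fold lower, 6.52 to 7.91), Col12a1 was 3.27-fold and Col1a1 2.69-fold lower. Without genes of the tendon and fibroblast lists, the matrix median was -0.74 with 34 of 36 lower. Here too, this cannot tell whether tendon tissue contributed to the rest. Tendon and cartilage had 12 of 13 lower and a median of -1.56, including Chad (13.2-fold), Kera (44.4-fold) and Tnmd (4.88-fold lower). Endothelial genes had 16 of 18 lower and a median of -0.85, with Kdr 2.79-fold and Pecam1, the platelet and endothelial adhesion molecule, 2.28-fold lower. Interferon response had 25 of 29 lower and a median of -0.63, with Rsad2 (3.88-fold) and Irf7 (3.70-fold). Fibroblast genes (-0.68), complement and coagulation (-0.61, C3 2.75-fold lower), growth factors (-0.43), smooth muscle (-0.26), hypoxia targets (-0.17) and erythroid and blood (-1.40) were lower as well.

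All 44 nuclear oxidative phosphorylation genes were higher in EXO than in vehicle soleus, none by 2-fold, with a median of 0.21 and Ndufa1, a complex I subunit, at 1.31-fold. Fast fibre genes had 17 of 18 higher and a median of 0.47, with Myh1 at 2.81-fold. The dystrophin complex list (0.21, 14 of 21 higher, Dtna at 1.34-fold) and immediate early genes (0.38, 14 of 24 higher) were higher too. So were cytokines and NF-kB targets (0.21, but -0.019 with no filter on low values) and keratinocyte genes (0.54, 5 genes, but 0 with no filter). Within the immediate early list Socs3 was 17.4-fold higher and Fosb 41.2-fold lower (51.0 to 1.24 CPM, 23.9 to 77.7). Il6, the main inducer of acute-phase genes, had 2 reads in vehicle and was 21.4-fold higher (5.50 to 184). Ribosomal proteins had a median of 0.02 with 21 of 34 higher, yet lay below random lists of equally abundant genes. Muscle regeneration (0.15), slow fibre (0.08), fatty acid use (0.07), glycolysis (0.18) and clock genes (-0.09) were not apart. Rescaling every library to the same total moved the median of all genes from 0.01 to -0.12 here and turned the ribosomal median to -0.11.

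Lars2 (chromosome 9, 123366927 to 123462666, GRCm38/mm10 with GENCODE vM21) showed the largest single difference, at 42.7 CPM in vehicle and 7895 in EXO soleus (185-fold, 170.2 to 202). Other genes higher in EXO soleus were Socs3 (15.9 to 276 CPM, 17.4-fold), Bcl3, a regulator of NF-kB (15.9-fold), Rpl30 (10.2-fold), Rrad (8.04-fold), Myc (6.56-fold), Slc10a6 (6.22-fold), Serpina3n, a secreted protease inhibitor (5.41-fold), Mt2 (5.15-fold) and Mt1 (4.83-fold). Chil1 was 11.4-fold lower. Hbb-bs (at least 129-fold lower), Plac9a (10.2-fold) and Plac9b (7.68-fold) share sequence and are uncertain, and Etohi1 (13.6-fold lower) and H2-Q9 (19.1-fold lower) could not be checked.

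The EXO heart library had lower immediate early and glucocorticoid-responsive genes than the vehicle heart, and higher interferon and clock genes. Atf3, Nr4a3 and Pdk4 were lower. Dbp, Lars2 and Myh7 were higher. The counts at 2-fold were 106 higher and 100 lower, and the majority turned to 37 higher and 52 lower with a mean of at least 5 CPM and to 19 and 40 with a pseudocount of 5 CPM.

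Immediate early genes had 23 of 24 lower, 10 at least 2-fold, and a median of -0.90. Atf3 went from 22.4 to 3.55 CPM (6.33-fold lower, 4.64 to 8.79) and Nr4a3, an orphan nuclear receptor, was 25.8-fold lower. Glucocorticoid targets had 14 of 16 lower and a median of -0.42, with Pdk4 from 619 to 158 CPM (3.91-fold lower). Cell cycle (-0.29, Mki67 2.39-fold lower), fatty acid use (-0.19, 27 of 30 lower), muscle regeneration (-0.18, but 0 with no filter on low values), the unfolded protein response (-0.17) and heat shock (-0.17) were lower. With a mean of at least 5 CPM the calls of cell cycle (-0.16), heat shock (-0.15) and muscle regeneration (-0.18) were lost. Interferon response had 27 of 29 higher and a median of 0.41, with Gbp3 at 2.09-fold. Clock genes (0.42), adipocyte genes (0.31, but -0.049 with a mean of at least 5 CPM), macrophage genes (0.25), antigen presentation (0.24), complement and coagulation (0.21, C3 at 1.42-fold), smooth muscle (0.18), growth factors (0.10), endothelial genes (0.09) and erythroid and blood (0.46) were higher. Cardiac stress genes were higher at a median of 0.13, with Myh7 from 1255 to 3672 CPM (2.92-fold, 2.87 to 2.98) and Nppa at 2.32-fold. Ribosomal proteins had a median of -0.002 and were called above random lists of like abundance, and with libraries rescaled to the same total the median was 0.06. The matrix list (-0.002, 20 of 41 higher) and fibroblast genes (0.03) were not apart in EXO heart, unlike in CDC heart, although Tnc was 4.03-fold lower in EXO.

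Other genes higher in EXO heart were Dbp (20.9 to 106 CPM, 5.05-fold, 4.45 to 5.75), Lars2 (4.16-fold), Ciart, a clock repressor (3.41-fold), Akr1c14 (3.22-fold) and Cxcl14 (2.66-fold). Adamts9, a matrix protease (4.01-fold), Arntl, the clock activator BMAL1 (4.18-fold), and Nfil3, a repressor of clock output (4.0-fold), were lower. Ccl21a, Hbb-bs, BC002163 and Rnaset2b (higher) and Hist1h4m (lower) share most of their sequence with other genes.

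**Figure D2:**
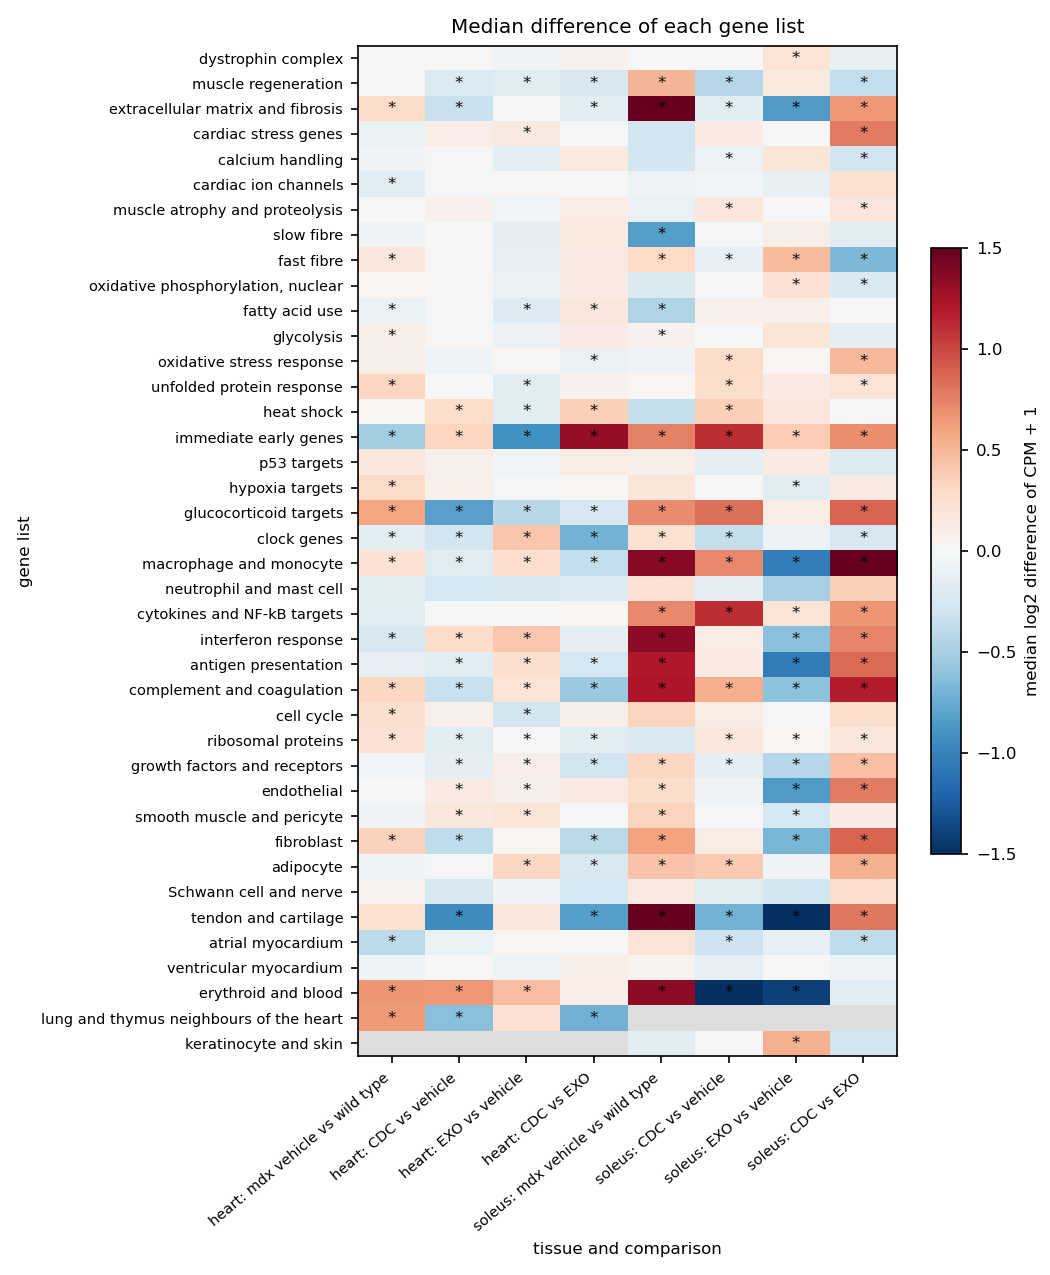
Median log2 difference of CPM + 1 (colour) of each ranked gene list in 4 comparisons per tissue, with an asterisk where the median lay outside 95% of random lists matched on expression and grey where fewer than 5 genes were measured. In soleus the matrix median is 1.62 for vehicle against wild type, -0.16 for CDC against vehicle and -0.85 for EXO against vehicle.

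**Figure D3:**
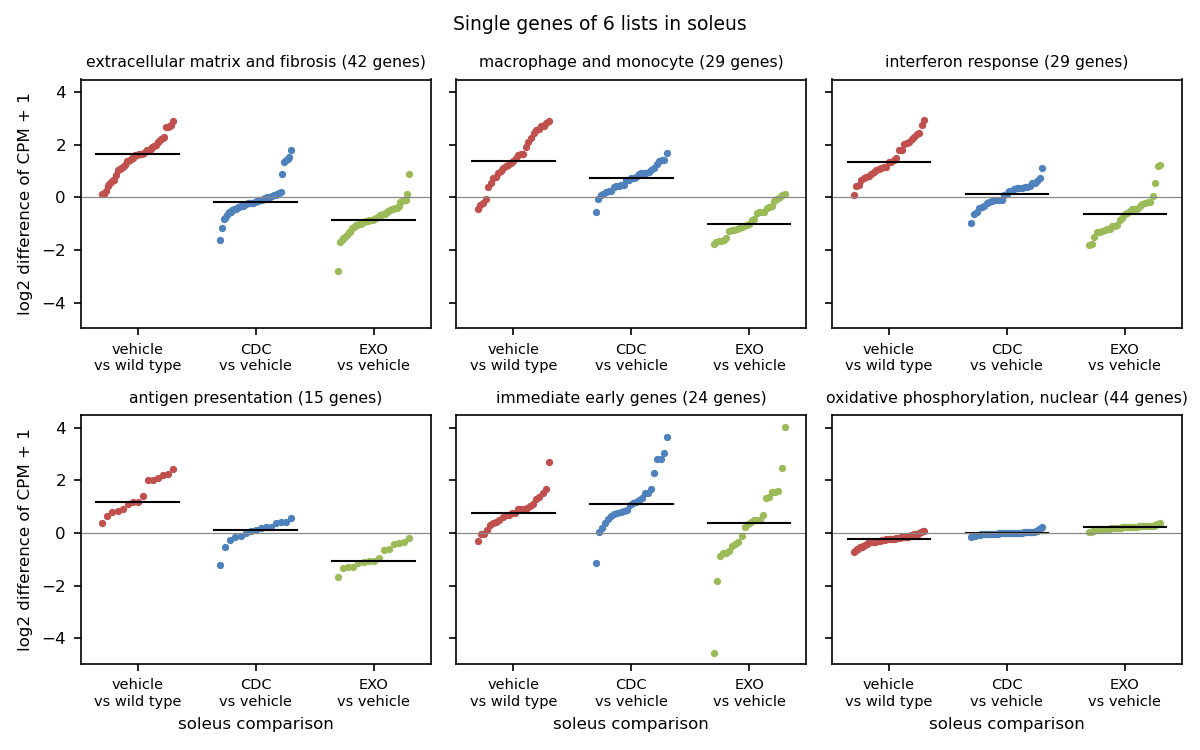
Log2 difference of CPM + 1 of each gene (points, sorted) of 6 lists in soleus for vehicle against wild type, CDC against vehicle and EXO against vehicle, with the median as a black line. Of 29 macrophage and monocyte genes, 25 are higher in vehicle than in wild type, 27 higher in CDC than in vehicle and 26 lower in EXO than in vehicle.

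Set directly against each other, the CDC soleus library lay above the EXO library most in macrophage and complement genes, and below it in fast fibre genes. Of 29 macrophage and monocyte genes, 28 were higher in CDC than in EXO, 25 of them at least 2-fold, with a median of 1.64 and Ctss at 7.99-fold (18.6 to 148 CPM, 6.88 to 9.31). All 18 endothelial genes were higher in CDC (median 0.78), and all 44 nuclear oxidative phosphorylation genes were lower (median -0.22). At least 2-fold differences numbered 614 higher and 206 lower in CDC.

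Complement and coagulation (1.17), glucocorticoid targets (0.88, 16 of 16 higher), fibroblast genes (0.87), antigen presentation (0.85, H2-Aa at 3.05-fold), tendon and cartilage (0.79), cardiac stress genes (0.78, but 0.11 and no call with no filter on low values, Atf3 at 14.8-fold), interferon response (0.73), immediate early genes (0.70, Fosb at 18.4-fold), cytokines (0.67), the matrix list (0.65, 38 of 42 higher), adipocyte genes (0.54), oxidative stress (0.49), growth factors (0.45), the unfolded protein response (0.19), ribosomal proteins (0.17) and muscle atrophy (0.16) were higher in CDC soleus. Fast fibre genes (-0.67, Myh2 2.09-fold lower), atrial genes (-0.38), muscle regeneration (-0.37, Myh8 3.72-fold lower), calcium handling (-0.29) and clock genes (-0.24) were lower. Ms4a6b, a gene of myeloid and lymphoid cells, was 14.4-fold higher in CDC, and Lars2 (289-fold), Dbp (6.95-fold), Ky (5.98-fold), G0s2, a lipase inhibitor (4.77-fold), Mir6236 (4.24-fold) and Per3 (4.08-fold) were lower.

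In heart the CDC library lay above the EXO library in immediate early genes and below it in clock, complement and macrophage genes. Of 24 immediate early genes, 23 were higher in CDC, 16 at least 2-fold, with a median of 1.32, among them Fos (14.7 to 91.3 CPM, 6.20-fold), Nr4a1 (4.84-fold) and Atf3 (6.97-fold). Clock genes had a median of -0.71, with 12 of 18 lower and 6 higher. Dbp (5.91-fold) and Per2 (5.61-fold) were lower and Arntl (6.37-fold) higher. There were 73 genes at least 2-fold higher and 214 at least 2-fold lower in CDC heart.

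Heat shock (0.36, 12 of 12 higher) and fatty acid use (0.17) were higher in CDC heart. Tendon and cartilage (-0.83), lung and thymus neighbours (-0.72), complement (-0.55, C4b 3.47-fold lower), fibroblast genes (-0.40), macrophage genes (-0.37), growth factors (-0.29), antigen presentation (-0.27), glucocorticoid targets (-0.25), muscle regeneration (-0.24), adipocyte genes (-0.23), the matrix list (-0.17), ribosomal proteins (-0.16) and oxidative stress (-0.10) were lower. The tendon, neighbour and regeneration medians were 0 with no filter on low values and the glucocorticoid median -0.077 with a mean of at least 5 CPM, all without a call. Cxcl1 (6.96-fold) and Xkrx (4.81-fold) were higher, and Ppbp (13.8-fold), Tubb1 (9.97-fold), Itga2b (7.08-fold), Inmt, a methyltransferase (6.99-fold), and Myh7 (3.25-fold) lower.

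**Figure D4:**
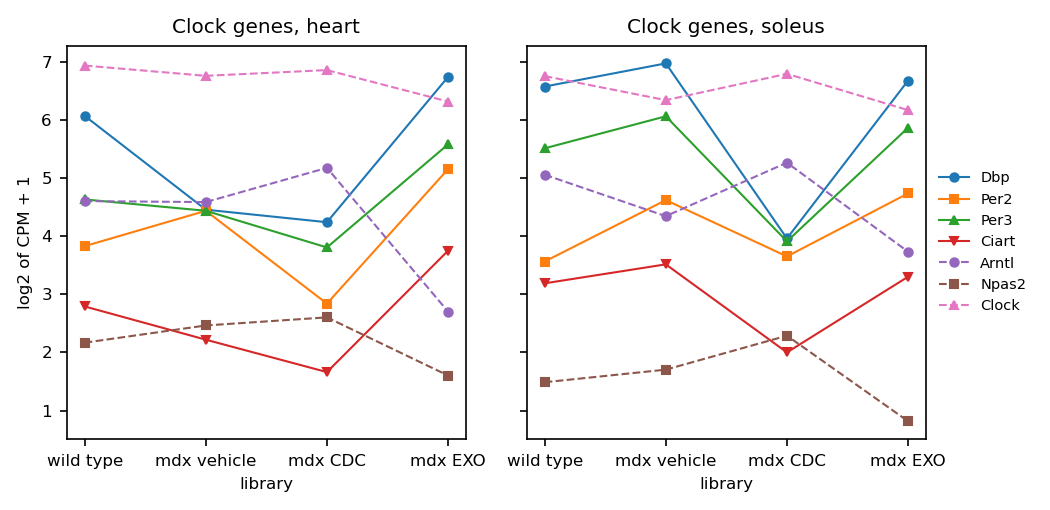
Log2 of CPM + 1 of 7 of the 18 listed clock genes, chosen after their values were seen, in the 4 libraries of each tissue, with solid lines for Dbp, Per2, Per3 and Ciart and dashed lines for Arntl, Npas2 and Clock. In both tissues the 4 solid lines lie lower and the 3 dashed lines higher in the CDC than in the EXO library, for example Dbp at 17.9 and 106 CPM in heart and 14.6 and 101 CPM in soleus.

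Several genes differed from vehicle by at least 2-fold in the same direction with both treatments. In soleus Socs3, Rrad, Rpl30, Bcl3, Myc, Serpina3n, Mt2 and Slc10a6 led the 60 genes higher in both, and Bcl6b, Aplnr and Col1a1, with haemoglobin genes, the 57 lower in both. In heart Akr1c14, Akap5, a scaffold for protein kinases, and Nppa were among the 29 higher in both, and Adamts9, Socs3, Tnc, Ell2 and Cdkn1a, a cell cycle inhibitor, among the 48 lower in both. Socs3 thus lay lower than vehicle in both treated hearts and higher in both treated soleus libraries. In heart it was high in vehicle alone, at 4.27 CPM in wild type, 31.3 in vehicle, 6.74 in CDC and 8.45 in EXO. In soleus it stood at 5.81 CPM in wild type, 15.9 in vehicle, 209 in CDC and 276 in EXO. Independent lists of these sizes would share 0.719 and 1.38 genes in heart and 2.79 and 7.92 in soleus, and 3 genes in heart and 9 in soleus differed in opposite directions, against 2.14 and 12.6.

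Both differences use the same vehicle library, so part of this overlap may come from that library alone. Across genes, which are not replicates, the CDC and EXO differences from vehicle correlated at r = 0.484 in heart (covariance 0.0656) and 0.365 in soleus (0.0781). Simulated unchanged groups gave r = 0.477 and 0.457 with counting error alone (covariance 0.0120 and 0.0133), and 0.497 and 0.490 with an assumed biological coefficient of variation of 0.2 (0.0816 and 0.0817), which also gave 21.1 and 24.2 shared 2-fold genes, against 0 and 0.1 with counting error alone.

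Genes that stood at least 2-fold apart between vehicle and wild type mostly differed from vehicle in the direction of wild type in the treated libraries, whether or not they passed the wild type level. In heart 242 of 270 genes (89.6%, Wilson interval 85.4% to 92.7%) differed toward wild type in CDC and 228 of 271 (84.1%, 79.3% to 88.0%) in EXO. In soleus 776 of 1284 (60.4%, 57.7% to 63.1%) did so in CDC and 1068 of 1285 (83.1%, 81% to 85.1%) in EXO. Choosing genes on the vehicle library favours this direction: groups simulated without any effect and with an assumed biological coefficient of variation of 0.2 gave 93.1% in heart and 93.2% in soleus. That simulation gave wild type and vehicle the same mean as well, with 195 genes at least 2-fold apart between soleus libraries. In the data 1286 stood apart between vehicle and wild type soleus. The simulated shares therefore cannot say what genes with a real difference from wild type would show without a treatment effect. Another mdx library in the role of vehicle gave 82.8% to 86.6% in heart and 57% to 89.6% in soleus. For genes chosen in the other tissue, the direction was also taken from that tissue, and the wild type library of the tissue itself was not used. Counted this way, 56.9% of genes in CDC heart differed against the direction of vehicle from wild type in soleus, with 48.6% for all genes. The shares were 37.8% in EXO heart against 50.3%, 36.7% in CDC soleus against 49.99% and 45.3% in EXO soleus against 49.9%.

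Counted without choosing genes on the vehicle library, 1286 genes in vehicle, 1681 in CDC and 912 in EXO soleus stood at least 2-fold from wild type, and 271, 196 and 273 in heart. Macrophage genes had medians against wild type soleus of 1.36 in vehicle, 2.07 in CDC and 0.57 in EXO. The matrix list had medians of 1.62, 1.27 and 0.76, and interferon response 1.34, 1.54 and 0.71. Endothelial genes had medians of 0.28, 0.20 and -0.67, with 16 of 18 below wild type in EXO. Slow fibre genes remained below wild type in all 3 mdx soleus libraries, at -0.82, -0.92 and -0.62. In vehicle, CDC and EXO soleus, muscle regeneration had medians of 0.51, 0.53 and 0.73, and erythroid and blood genes 1.35, -0.10 and 0.07. In heart the matrix medians against wild type were 0.28 in vehicle, 0.05 in CDC and 0.29 in EXO. The atrial list lay below wild type in all 3 mdx hearts, at -0.39, -0.23 and -0.30 in the same order.

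Differences in heart and soleus correlated weakly across genes. For vehicle against wild type r was 0.112, and 52 of the 72 genes at least 2-fold apart in both tissues had the same sign. For CDC against vehicle r was -0.0948 with 17 of 56 genes of the same sign, and for EXO against vehicle -0.0568 with 32 of 51. Genes higher in both tissues numbered 40 for vehicle against wild type, 10 for CDC and 9 for EXO, against 9.49, 1.98 and 0.587 for independent lists of these sizes, and genes lower in both 12, 7 and 23, against 1.10, 2.69 and 2.62. Depending on the comparison, 16 to 24 of 39 ranked lists stood apart from random lists, against 1.95 by chance if genes were independent, which genes of a list are not.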

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

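All tests in this part were chosen only after the result was seen, and with 1 library per group none of them separates a treatment from other differences between animals. The following lists were called apart in opposite directions in heart and soleus under the same comparison, with medians of at least 0.2 in size in both, and the difference between the tissues was not tested.

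For vehicle against wild type, immediate early genes had a median of -0.53 in heart and 0.76 in soleus, a difference of 1.29, and interferon response genes -0.24 and 1.34, a difference of 1.58. Egr1, a first responder to stimulation, was 2.64-fold higher in vehicle soleus, and Cyr61 2.82-fold lower in vehicle heart. For CDC against vehicle, glucocorticoid targets had a median of -0.82 in heart and 0.83 in soleus, a difference of 1.64, with Fkbp5 at 5.16-fold lower and 3.75-fold higher. Complement and coagulation genes had medians of -0.33 and 0.55, a difference of 0.88. Erythroid and blood genes had medians of 0.65 and -1.59, a difference of -2.24, with Hba-a1 3.57-fold lower in CDC soleus. Against wild type soleus, however, the erythroid median was 1.35 in vehicle and -0.10 in CDC, the latter not apart.

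For EXO against vehicle, immediate early genes had a median of -0.90 in heart and 0.38 in soleus (14 of 24 higher), a difference of 1.28. Immune genes went the other way. Macrophage and monocyte genes had medians of 0.25 and -1.03, a difference of -1.28, interferon response 0.41 and -0.63, a difference of -1.03, antigen presentation 0.24 and -1.04, a difference of -1.28, and complement and coagulation 0.21 and -0.61, a difference of -0.82. Erythroid and blood genes had medians of 0.46 and -1.40, a difference of -1.86. In EXO soleus their median against wild type was 0.07, not apart. Opposite calls with a smaller median in a tissue were those of clock genes for vehicle against wild type (-0.18 in heart and 0.23 in soleus), of macrophage (-0.18 and 0.72) and ribosomal protein genes (-0.16 and 0.17) for CDC against vehicle, and of growth factors (0.10 and -0.43), endothelial (0.09 and -0.85), smooth muscle (0.18 and -0.26) and ribosomal protein genes (-0.0021 and 0.02) for EXO against vehicle.

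Macrophage genes were lower in EXO and higher in CDC than in vehicle soleus, and a shift in the share of muscle fibre RNA was weighed against this. A smaller share in CDC would raise the genes of every other cell type alike. Macrophage genes lay 0.72 above endothelial and fibroblast genes (bootstrap interval 0.30 to 0.97), although not clearly above adipocyte genes (0.32, -0.07 to 0.60). Between these libraries, this argues against a smaller share as the whole cause. The bootstrap resampled the genes of a list, which are not replicates, so its intervals do not cover variation between libraries or animals. Scaling moves all genes alike, but the macrophage median of EXO against vehicle lay apart from that of all genes by -1.04 (-1.23 to -0.58). As the median of all genes was 0.0073, this restates the list median of -1.03 and is no separate test. A larger share in EXO cannot be told apart from other causes: macrophage minus endothelial and fibroblast genes was -0.30 (-0.53 to 0.26), while macrophage minus smooth muscle genes was -0.77 (-1.001 to -0.24), minus adipocyte genes -0.98 (-1.19 to -0.32) and minus Schwann cell genes -0.76 (-1.02 to -0.21), lists with members that muscle fibres may also express. Macrophage minus tendon and cartilage genes went the other way in EXO, at 0.52 (-0.30 to 1.52). An effect of treatment, of the piece of muscle sampled or of the single animals stays open as well.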

How the results depend on the processing

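No paired analysis was possible because the libraries carry no replicate numbers and each comparison within a tissue has 1 library per group, so no replicate could be left out either. A fit of both tissues with tissue as a block was not made, since it would take heart and soleus as replicates of each other. Depth limits single genes: 1 CPM stood for 9.98 to 13.9 reads, and 3 reads made 0.215 to 0.301 CPM. Where a value below moved, the cause was not tested, except that a filter at 5 CPM leaves fewer genes to count and a pseudocount shrinks or widens the ratios of low values by construction. Under the alternatives chosen before the data were examined and the 2 kinds of count added after seeing the data, 1603 medians of called lists, each counted once per alternative, kept direction and call, 66 lost the call without a change of sign, and 6 changed sign. Of the lists given above, calls were lost under at least 1 alternative in heart for fast fibre, glycolysis, lung and thymus neighbours and cell cycle (vehicle against wild type), muscle regeneration, antigen presentation, tendon and the neighbours (CDC against vehicle), muscle regeneration, heat shock, ribosomal proteins, growth factors and cell cycle (EXO against vehicle) and the neighbours, muscle regeneration, tendon and glucocorticoid targets (CDC against EXO), and in soleus for muscle atrophy and growth factors (CDC against vehicle), cytokines, keratinocyte genes and ribosomal proteins (EXO against vehicle) and cardiac stress genes (CDC against EXO). By alternative, 3 calls were lost with a pseudocount of 0.5 CPM, 12 with 5 CPM, 21 with no filter, 22 with a mean of at least 5 CPM, 2 with the same total, 1 with median-of-ratios scaling and 5 with random lists in 5 bins. Of the differences of single named genes 2100 stayed on the same side of 2-fold and 36 crossed it. None of at least 2-fold changed sign, and changes of sign in smaller differences were not counted. Of the other values 254 stayed and 72 moved. Every count stayed within 1.5 times of the reported one with median-of-ratios scaling, without genes sharing at least 50% of their sequence and with a test on counting error added.

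With a pseudocount of 0.5 CPM, genes at least 2-fold apart in heart numbered 411 for vehicle against wild type (271 with 1 CPM), 415 for CDC against vehicle (273), 338 for EXO against vehicle (206) and 326 for CDC against wild type (196), and genes with 1 heart library apart numbered 61 for wild type (36), 59 for vehicle (34) and 53 for CDC (30). With 5 CPM the 2-fold counts in heart were 80 for vehicle against wild type, 93 for CDC and 59 for EXO against vehicle, 82 for CDC against EXO (287), and 55 for CDC and 89 for EXO (273) against wild type. In soleus they were 440 for vehicle against wild type (1286), 223 for CDC (590) and 161 for EXO (530) against vehicle, 294 for CDC against EXO (820), and 757 for CDC (1681) and 297 for EXO (912) against wild type. The split became 19 higher and 40 lower for EXO against vehicle heart, 32 and 50 for CDC against EXO heart, 181 and 42 for CDC against vehicle soleus and 255 and 39 for CDC against EXO soleus. Genes with 1 library apart numbered 13, 12, 4 and 8 (27) for wild type, vehicle, CDC and EXO heart, and 112 (406), 16 (47), 88 (195) and 22 (58) in soleus. The share toward wild type was 57.4% in CDC soleus (60.4%) and 87.2% in EXO soleus (83.1%). For genes and directions taken from soleus, the share in EXO heart was 32.5% (37.8%). The correlation of the CDC and EXO differences was 0.462 in heart and 0.348 in soleus, and between tissues -0.130 for CDC (-0.0948) and -0.0752 for EXO (-0.0568).

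With no filter, the median of cytokines and NF-kB targets for EXO against vehicle soleus was -0.019 instead of 0.21, the correlation of CDC and EXO differences in soleus was 0.381 (0.365), and the correlation between tissues was 0.0826 for vehicle against wild type (0.112) and -0.0719 for CDC.

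With a mean of at least 5 CPM, the adipocyte median for EXO against vehicle heart was -0.049 instead of 0.31, and the hypoxia median for EXO against wild type soleus 0.045 instead of -0.26. The split for EXO against vehicle heart was 37 higher and 52 lower. The 2-fold counts in heart were 131 for vehicle against wild type, 150 for CDC and 89 for EXO against vehicle, 146 for CDC against EXO, and 86 for CDC and 138 for EXO against wild type. In soleus they were 775, 363, with 249 higher and 114 lower, 294, 509, 1076 and 559 in the same order. Genes with 1 library apart numbered 19 for wild type, 19 for vehicle, 14 for CDC and 16 for EXO in heart, and 23 for vehicle and 35 for EXO in soleus. The share toward wild type was 56.7% in CDC soleus. For genes and directions taken from heart, the share in EXO soleus was 37.9% (45.3%). The correlation of CDC and EXO differences in soleus was 0.349, and between tissues it was 0.134 for vehicle against wild type, -0.114 for CDC and -0.0316 for EXO.

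With libraries rescaled to the same total, the ribosomal medians for EXO against vehicle were 0.064 in heart (-0.0021) and -0.11 in soleus (0.02), and the nuclear oxidative phosphorylation median for EXO against wild type soleus was 0.19 (-0.03). The share toward wild type was 87.6% in EXO soleus. For genes and directions taken from soleus, the share in EXO heart was 32.8%. Dmd against wild type was -1.30 in EXO heart (-1.39), and -1.40 in vehicle (-1.76), -1.36 in CDC (-1.67) and -1.33 in EXO soleus (-1.56), lower than wild type as before. The split for vehicle against wild type soleus, given with that comparison, was 1750 higher and 74 lower, and for EXO against vehicle heart 160 higher and 103 lower (106 and 100).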

Other observations

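Some platelet genes were highest in the vehicle and EXO heart libraries, and were chosen after their values were seen. Ppbp, a platelet chemokine, stood at 18.8 CPM in vehicle and 17.2 in EXO heart but at 1.55 in wild type and 1.25 in CDC heart, and Tubb1, the platelet tubulin, and Itga2b and Itgb3, platelet integrins, were likewise highest in vehicle, then EXO heart. Pf4, another platelet chemokine, differed by less, at 14.1 CPM in vehicle, 10.8 in EXO, 7.76 in wild type and 9.49 in CDC heart. The coagulation factor F5 stood at 8.46 CPM in vehicle heart and at 0.679 in wild type, 0.333 in CDC and 2.87 in EXO heart. No list of platelet genes was ranked.

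All tests in the paragraphs that follow were chosen only after the result was seen. Lars2 and the ribosomal RNA precursor Rn45s were both highest in the EXO library of each tissue. Lars2 stood at 170.4, 249.8, 363 and 1039 CPM in wild type, vehicle, CDC and EXO heart and at 422, 42.7, 27.4 and 7895 in soleus, and Rn45s at 2324, 3131, 3042 and 4706 and at 2808, 6545, 5313 and 18446. Ribosomal RNA reads counted in Lars2 in a fixed ratio to Rn45s would keep the ratio of these genes, but it ranged 83.1-fold among the soleus libraries, from 0.00515 in CDC to 0.428 in EXO. In heart the ratio ranged less, from 0.0733 in wild type to 0.221 in EXO. An effect of EXO cannot be told apart from a difference between libraries, since wild type over vehicle soleus, without any EXO, was already 9.89-fold. A ribosomal contribution in another ratio was not tested and may remain.

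Clock genes lay apart between the CDC and EXO libraries in both tissues. A scaling difference would move them all the same way, but of the 18 genes of the clock list 3 were at least 2-fold higher and 6 at least 2-fold lower in CDC than in EXO heart, and 3 and 5 in soleus, each beyond counting error. Different times of day at collection cannot be told apart from other causes: 14 of 18 genes differed in the same direction in both tissues, which an effect of treatment could also bring, and the labels do not give the times. An effect of the treatments on the clock cannot be told apart either. Vehicle and wild type heart, neither given cells or exosomes, already differed by a mean absolute log2 difference of 0.46 over the list (0.45 in soleus). Between CDC and EXO this difference was 1.16 in heart and 0.95 in soleus.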
